A study of Homo sapiens with 10 samples.

How the data were processed

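Human 697 pre-B leukaemia cells were profiled by RNA-seq in 4 libraries, 2 control and 2 treated with TPA at 0.5 µg/ml, and by ChIP-seq in 6 further samples (2 for CTCF, 2 for linker histone H1 and 2 input DNA libraries). Samples were assigned to groups and replicate numbers from their titles in the labels. Only the RNA libraries were analysed; the 6 ChIP and input samples were not analysed here.

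The authors deposited 1 table with a value in RPKM (reads scaled to transcript length and library size), per the file headers, for each of 27142 genes in each RNA library. Each gene had 1 RefSeq accession, a symbol and a cytogenetic band, and values were given to 3 decimals. Reads were handled with CASAVA 1.8, Bowtie 1.12, TopHat, SAMtools and HOMER on the human build hg19, per the submitters' processing notes, which do not give the role or order of each tool. Whether strand was used, how reads that map to several places were treated and whether the hg19 index held its alternate haplotype sequences were not given in the sources used here. Values of overlapping genes and of near-identical copies (histone genes, for example) are therefore uncertain.

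RPKM values are not counts, so no count model was fitted. Totals of reads were not given, but low values of a gene move in steps of what 1 read is worth. The ratio of these steps between libraries (genes between 0.03 and 0.15 RPKM in both) gave the depth relative to control replicate 1, which was 97.4% for control replicate 2, 97.8% for TPA replicate 1 and 91.3% for TPA replicate 2. The absolute depth stays unknown, so no counting interval is given for any value. Of the genes, 7027 were listed at 0 in all 4 libraries. Of 81 ribosomal protein and reference genes in the table, 1 (RPS18) was at 0 in at least 1 library, so a gene at 0 is described only as listed at 0. Among 1360 genes with a mean of 50 RPKM or more, 51.3% differed by over 10% between the control replicates and 66.5% between the TPA replicates, so the replicates were not treated as copies of 1 library.

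Genes with at least 1 RPKM in at least 2 of the 4 libraries were kept, which left 12159 (10767 protein-coding and 1392 others). Values were transformed to log2(RPKM + 1), with no further scaling, and fitted in R 4.3.3 with limma 3.58.1 (TPA minus control, empirical Bayes with a mean-variance trend, 2 residual and 5.88 prior degrees of freedom). P-values are two-sided and were adjusted by the Benjamini-Hochberg method over all genes tested. With 2 libraries per group an exact permutation test cannot give a two-sided p under 0.333, so none was used for single genes. Gene lists were compared with the other genes by limma's camera with a preset correlation of 0.01, over lists with at least 5 tested members, and again with a correlation estimated from the data, and limma's fry (with statmod 1.5.0) was run as a test of direction. With an estimated correlation camera works with only the 2 residual degrees of freedom, so a list that fails there is not shown to be unmoved. Figures were drawn with matplotlib 3.10.9.

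Before the data were examined, 30 gene lists were fixed (immediate early genes, ERK feedback, NF-κB targets, pre-B identity, mature B and plasma cells, MHC class II, interferon response, S phase, mitosis, cyclins and CDK inhibitors, p53 targets, BCL2 family, MYC and ribosome biogenesis, ribosomal proteins, linker histones, core histones, histone chaperones, CTCF and cohesin, phorbol ester receptors, adhesion, cytokines, cholesterol synthesis, glycolysis, oxidative phosphorylation, unfolded protein response, T-cell, myeloid and erythroid markers, and reference genes, with 1 list that is not reported here). The rule for the genes named was fixed then too. It takes the 10 largest rises and 10 largest falls among genes with an adjusted p under 0.05, a mean of at least 5 RPKM and no overlap between groups, the 2 members with the smallest p in each direction of each list, and a fixed set (CTCF, the linker histone genes, NAP1L1, NAP1L4, EGR1, FOS, JUN, MYC, RAG1, RAG2, VPREB1, IGLL1, DNTT, PAX5, EBF1, PRKCB, CD79A, MS4A1, ACTB and GAPDH, among others). Other list members named as examples of a group, and members named because they moved against it, were chosen after their values were seen.

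The alternatives tried were pseudocounts of 0.1 and 0.5, no filter and a filter at 5 RPKM, median-of-ratios scaling, quantile normalization, limma without the trend and with robust estimation, adjusted p thresholds of 0.01 and 0.1, limma's treat against a 1.2-fold change, the replicate number as a block, each library left out in turn and, added after seeing the data, protein-coding genes only. Leaving out 1 library leaves a group with 1, which is assumed to vary like the other. Without either control replicate the prior degrees of freedom became infinite, against 5.88 with all libraries. The p-values of those fits therefore cannot be set against the main ones. For the replicate difference of hypoxia-response genes, a comparison with random lists and a test of scaling were also run; the first was set aside because the list was chosen after the values were seen, as were the list tests of the gene families chosen that way, and the verdict of the second was left out to keep the weighing to 3 patterns. For a weaker overall response in TPA replicate 2, the rule of the test was changed to allow for the quartiles after its first result was seen.

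The fit was tested on simulated data for the 12159 genes of this comparison, with 2 libraries per group and 200 changed genes in each of 10 simulations. It found 24.8% of the genes with a simulated log2 change of 0.5, 98.6% of those with 1 and 100% of those with 2, and 8.65% of its calls were false. Changes were planted only in genes above a set control level, so the shares found do not hold for genes low in control. The 200 changed genes were also a far smaller share than the 58.2% called in the data. The share of false calls therefore does not carry over to those calls. Of 280 tests of lists with no planted change 0 passed with camera, and a list with a planted change was found in 10 of 10 simulations. The simulated genes varied independently of one another. The simulation therefore cannot show how often camera passes lists falsely where members vary together, and no such rate is drawn from it.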

Results

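The series profiled 697 cells, a human pre-B acute lymphoblastic leukaemia line, with and without 12-O-tetradecanoylphorbol-13-acetate (TPA), a phorbol ester that binds and activates protein kinase C. Of its 10 samples, 4 were RNA-seq libraries, in 2 control and 2 TPA replicates, and these are the measurements compared here. The other 6 were 2 CTCF ChIP-seq libraries, 2 linker histone H1 ChIP-seq libraries and 2 input DNA libraries, which were not analysed here. TPA was used at 0.5 µg/ml, and the labels give its duration only as a range from 0 to 24 h. Each gene of each RNA library had 1 value in RPKM, a read count scaled to gene length and library size. Summed RPKM was 370558 and 386700 in the control libraries and 349438 and 388846 in the TPA libraries. A value of 1 RPKM or more was listed for 11464 and 11449 genes in the controls and for 11774 and 11878 with TPA. The number of reads behind the libraries was not given, but the steps between low values placed the depth of control replicate 2 at 97.4%, TPA replicate 1 at 97.8% and TPA replicate 2 at 91.3% of that of control replicate 1.

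The comparison of TPA with control asked which transcripts differ after phorbol ester treatment of these leukaemic B-cell precursors. MS4A1, which encodes the mature B-cell antigen CD20, rose from 0.736 ± 0.146 RPKM in control to 291 ± 13.0 RPKM with TPA (mean ± SD, n = 2 libraries per group, as for every such value that follows). The surrogate light chain genes IGLL1 and VPREB1, whose products form the pre-B-cell receptor, fell from 457 ± 3.14 to 8.97 ± 5.81 RPKM and from 347 ± 12.9 to 13.6 ± 9.23 RPKM. DNTT, which encodes the terminal transferase that adds nucleotides at antigen receptor joins, fell from 789 ± 19.5 to 26.0 ± 16.1 RPKM. The S-phase genes TYMS and PCNA fell 29.2-fold and 15.8-fold.

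Among genes with a mean of at least 5 RPKM, the 10 with the largest rise also included MB, RGS1, RGS2, TNFRSF9, EGR2 and MMP7. MB, the gene of the oxygen-binding protein myoglobin (22q12.3), had 0.585 ± 0.211 RPKM in control and 692 ± 77.9 RPKM with TPA, a log2 fold change of 8.77 (SE 0.156, adjusted p = 8.74e-08). RGS1 and RGS2, regulators of G-protein signalling (both 1q31.2), rose from 0.762 ± 0.302 to 306 ± 37.6 and from 9.94 ± 1.36 to 849 ± 96.5 RPKM. The costimulatory receptor gene TNFRSF9 (4-1BB, 1p36.23) rose from 0.072 to 116 ± 2.68 RPKM, and the zinc finger transcription factor gene EGR2 (10q21.3) from 0.343 to 124 ± 0.468 RPKM. The protease gene MMP7 (11q22.2) reached 139 ± 61.9 RPKM from 0.0485, with the widest spread relative to its mean among these 10 genes. KIR3DX1 (19q13.42), LINC01547 (21q22.3) and OCSTAMP (20q13.12) completed the set, with TPA means of 127, 133 and 79.5 RPKM against 0.467, 0.701 and 0.055 RPKM in control.

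The 10 largest falls were those of IGLL1 (22q11.23) and VPREB1 (22q11.22), DNTT (10q24.1), the metallothionein gene MT1G (16q13) and 6 genes tied to S phase. IGLL1 had a log2 fold change of -5.66 (SE 0.343, adjusted p = 5.42e-06) and DNTT of -5.01 (SE 0.352, adjusted p = 1.16e-05). MT1G fell from 116 ± 9.56 to 3.38 ± 1.32 RPKM. GINS2 (16q24.1), a subunit of the replicative helicase, fell from 107 ± 6.57 to 2.86 ± 0.144 RPKM, and RRM2 (2p25.1), a subunit of ribonucleotide reductase, from 86.8 ± 10.7 to 2.90 ± 0.053 RPKM. E2F1 (20q11.22), a transcription factor of S-phase genes, DTL (1q32.3), an adaptor of a replication-coupled ubiquitin ligase, and FAM111B (11q12.1) had log2 fold changes of -4.64, -4.65 and -4.97. TYMS (18p11.32), the thymidylate synthase gene, fell from 370.2 ± 59.6 to 12.7 ± 1.51 RPKM; it overlaps ENOSF1 and TYMSOS, which had log2 fold changes of -4.39 and -4.03, and no source used here says that reads were assigned by strand.

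**Figure D1:**
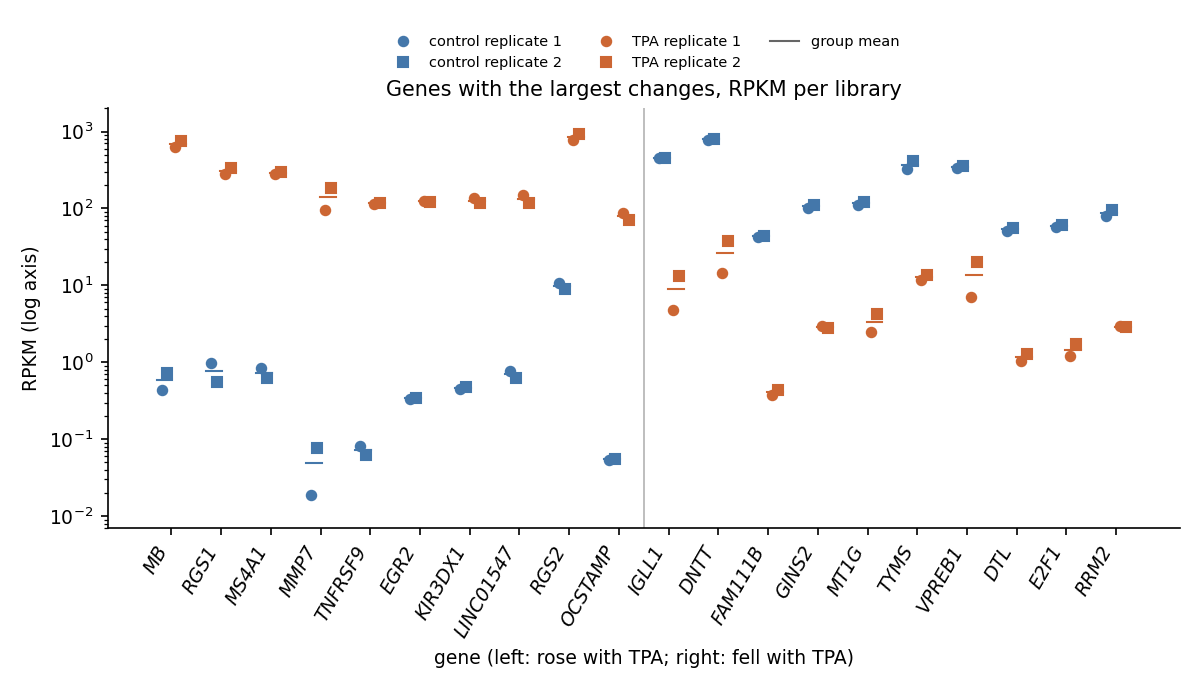
RPKM of each library (points; vertical log axis) for the 10 genes with the largest rise and the 10 with the largest fall under TPA (horizontal axis), with control libraries in blue, TPA libraries in orange and short lines at the group means. The 2 libraries of a group lie close together beside the gap between groups, and the TPA libraries lie farthest apart for MMP7, IGLL1, DNTT and VPREB1.

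Across the genome, 12159 genes had at least 1 RPKM in at least 2 libraries and were tested with limma on log2(RPKM + 1). At a Benjamini-Hochberg adjusted p under 0.05, 7075 genes changed (58.2%), of which 3454 rose and 3621 fell. A change of at least 2-fold on this scale was reached by 1428 genes that rose and 1397 that fell, and of at least 4-fold by 464 and 387. The groups did not overlap for 9703 of the genes tested (79.8%, against 33.3% by chance). Between replicates, the correlation over these genes was 0.993 for control and 0.988 for TPA, and between groups it was 0.798 to 0.816; these are correlations across genes, which are not independent replicates. The median difference between replicates was 0.128 in control and 0.184 with TPA on the log2 scale, against 0.485 to 0.539 between groups. No label says that the replicates were separate cultures, so every p-value measures only the spread between these samples, which may be technical. Fold changes on the log2(RPKM + 1) scale understate the change of genes with low values.

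**Figure D2:**
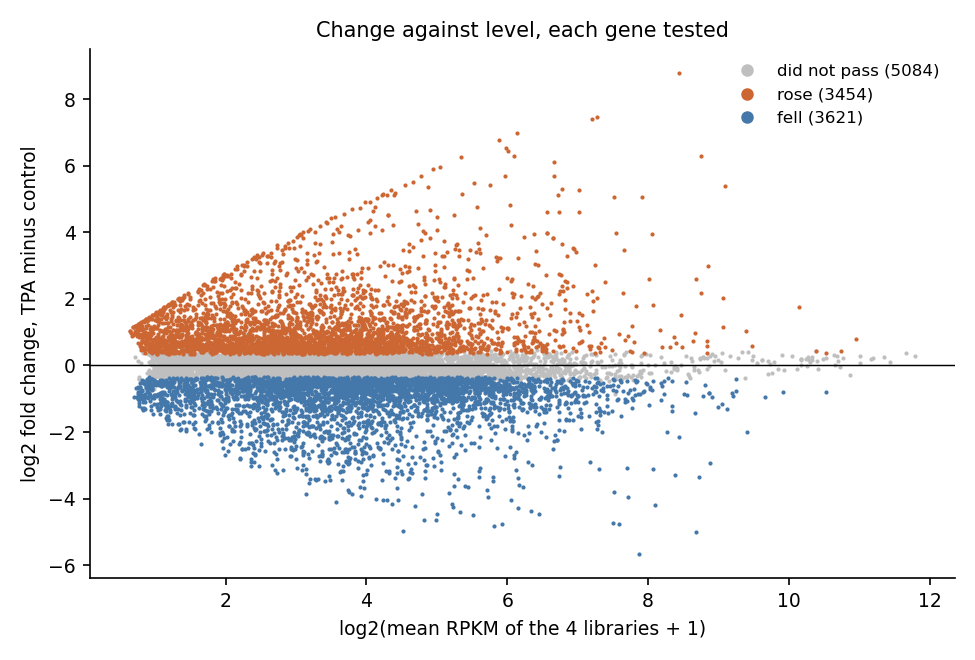
Log2 fold change, TPA minus control (vertical axis), against the log2 of the mean RPKM of the 4 libraries plus 1 (horizontal axis) for the 12159 genes tested; each point is a gene, orange where it rose, blue where it fell and grey where it did not pass. The 3454 rises and 3621 falls spread to both sides of 0, and the median of all genes is -0.024.

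Genes of the pre-B stage moved in both directions. The recombinase genes RAG1 and RAG2 fell from 37.4 ± 1.08 to 4.62 ± 2.43 and from 44.0 ± 2.72 to 4.07 ± 2.25 RPKM, and the interleukin-7 receptor gene IL7R fell from 143 to 18.0 RPKM. The adaptor gene BLNK and TCL1A fell with log2 fold changes of -3.34 and -3.07. EBF1 and PAX5, transcription factor genes that act in B-lineage identity, also fell, by less. EBF1 had a log2 fold change of -1.70 and PAX5 of -1.20. In contrast, the receptor signalling gene CD79A rose from 208 ± 13.2 to 858 ± 49.6 RPKM, the kinase gene BTK from 3.71 to 36.0 RPKM, and CD9 from 154 to 703 RPKM. Of the 33 pre-B identity genes tested, 9 rose, 19 fell and 5 did not pass, and 9 rose and 19 fell when adjusted over the list alone, with a median log2 fold change of -1.08 (camera, adjusted p = 0.0735; adjusted p = 0.699 with an estimated correlation). The list did not pass, but it passed with no filter on low values (camera, adjusted p = 0.0436). Its call also changed in each fit with 1 library left out. Its median was then -1.09 without control replicate 1, -1.015 without control replicate 2, -0.872 without TPA replicate 1 and -1.295 without TPA replicate 2.

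Most genes of mature B and plasma cells rose. Of 24 tested, 20 rose, 3 fell and 1 did not pass, and 20 rose and 3 fell when adjusted over the list alone (camera, adjusted p = 2.74e-07; adjusted p = 0.392 with an estimated correlation). Beside MS4A1, the Oct-2 gene POU2F2 rose from 0.378 to 56.2 RPKM, the leukocyte tetraspanin gene CD37 from 0.018 to 29.5 RPKM, and the Ets factor gene SPIB from 4.33 to 91.5 RPKM. The 3 that fell were the secretory genes JCHAIN, which joins the chains of polymeric immunoglobulin (464 to 180.0 RPKM), MZB1 (91.3 to 47.1 RPKM) and XBP1 (116 to 67.2 RPKM).

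Most class II antigen presentation genes rose. Of 12 tested, 11 rose, 1 fell and 0 did not pass, and 11 rose and 1 fell when adjusted over the list alone (camera, adjusted p = 3.55e-05; adjusted p = 0.514 with an estimated correlation). HLA-DQA1 rose from 5.45 ± 0.222 to 96.8 ± 23.5 RPKM, the invariant chain gene CD74 from 518 ± 80.6 to 1738 ± 189 RPKM, and CIITA, the class II transactivator gene, from 6.96 ± 0.0276 to 41.9 ± 3.02 RPKM. RFXAP, a subunit of the RFX complex that binds class II promoters, fell from 11.9 to 4.94 RPKM. The HLA genes lie in the bands 6p21.32 and 6p21.33, where 11 of 130 protein-coding genes averaged 1 RPKM or more, against 28 of 46 in the adjoining band 6p21.31. All 6 class II genes tested in these bands rose, and of the 6 outside them 5 rose and 1 fell.

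The genes of DNA replication and mitosis fell as a whole. All 48 S-phase genes tested fell, with a median log2 fold change of -3.15, and all 48 fell when adjusted over the list alone (camera, adjusted p = 6.79e-24; adjusted p = 0.401 with an estimated correlation). The replicative clamp gene PCNA fell from 393 ± 69.3 to 24.8 ± 6.85 RPKM, the helicase genes MCM4 and MCM3 from 153 to 6.44 and from 193 to 18.5 RPKM, and CDC6, which loads the helicase, from 60.3 to 1.75 RPKM. All 45 mitosis genes tested also fell, likewise all 45 adjusted over the list alone, with a median of -2.48 (camera, adjusted p = 3.82e-21; adjusted p = 0.401 with an estimated correlation). NUSAP1, a spindle protein gene, fell from 137 to 9.97 RPKM, AURKB from 101 to 8.17 RPKM, CDK1 from 101 to 8.82 RPKM and the proliferation marker MKI67 from 13.8 to 1.46 RPKM.

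Cyclins and their inhibitors outside those lists mostly fell too. Of 13 tested, 2 rose, 8 fell and 3 did not pass, and 2 rose and 8 fell when adjusted over the list alone (camera, adjusted p = 0.0325; adjusted p = 0.686 with an estimated correlation). CCND3, the D-type cyclin gene with the highest level here, fell from 604 ± 38.4 to 61.7 ± 11.7 RPKM. The inhibitor genes CDKN1A, CDKN2C and CDKN2D, whose products slow the cycle, fell as well, with log2 fold changes of -1.08, -2.19 and -2.56. The genes that rose were RB1 (55.4 to 110.0 RPKM) and CCNG2 (11.1 to 28.4 RPKM). CDKN1B did not pass, with 14.7 RPKM in control and 17.3 RPKM with TPA.

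Immediate early genes, which growth signals induce within minutes, were mostly higher. Of 22 tested, 16 rose, 3 fell and 3 did not pass, and 16 rose and 4 fell when adjusted over the list alone (camera, adjusted p = 2.28e-04; adjusted p = 0.401 with an estimated correlation). EGR1 rose from 1.32 ± 0.428 to 122 ± 45.4 RPKM and the antiproliferative gene BTG2 from 4.96 ± 1.75 to 203 ± 16.5 RPKM. FOS had 0.406 RPKM in control and 6.10 RPKM with TPA, a log2 fold change of 2.33. JUN did not pass (1.58 to 1.15 RPKM, log2 fold change -0.26, adjusted p = 0.119), although it did after quantile normalization (adjusted p = 0.0159). ATF3, KLF4 and FOSL2 fell.

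Feedback genes of the ERK pathway, which protein kinase C feeds into, rose in 12 of 14 cases. In this list 12 rose, 1 fell and 1 did not pass, and 12 rose and 1 fell when adjusted over the list alone (camera, adjusted p = 6.17e-06; adjusted p = 0.392 with an estimated correlation). PHLDA1 rose from 1.89 ± 0.0926 to 199 ± 31.1 RPKM, the ERK phosphatase genes DUSP2 and DUSP6 from 5.73 to 125 and from 37.5 to 191 RPKM, and SPRY1, a Sprouty inhibitor gene, from 2.63 to 59.2 RPKM. DUSP1 fell from 32.8 to 17.8 RPKM. ETV5 did not pass (107 to 101 RPKM).

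Among 26 tested NF-κB target genes, 16 rose, 5 fell and 5 did not pass, and 16 rose and 6 fell when adjusted over the list alone (camera, adjusted p = 0.00453; adjusted p = 0.477 with an estimated correlation). TRAF1 rose from 0.966 to 30.1 RPKM, the chemokine gene CCL3 from 0.0275 to 9.38 RPKM and the caspase-8 regulator gene CFLAR from 4.99 to 28.0 RPKM. NFKBIA, the gene of the inhibitor IκBα, fell from 27.5 to 9.93 RPKM, and CD83 from 24.1 to 5.51 RPKM. TNF, LTA and LTB were listed at 0 in every library, as was the immediate early gene IER3; all 4 lie in 6p21.33, in the stretch with few listed values.

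The phorbol ester receptor list holds genes of protein kinase C and D, RASGRP proteins, diacylglycerol kinases, MARCKS and MARCKSL1. Not all of these are phorbol ester receptors, and its members went both ways. Of 16 tested, 3 rose, 2 fell and 11 did not pass, and 3 rose and 2 fell when adjusted over the list alone (camera, adjusted p = 0.401; adjusted p = 0.666 with an estimated correlation). The protein kinase D genes PRKD2 and PRKD3 rose from 10.1 ± 0.308 to 105 ± 21.6 and from 23.8 ± 1.90 to 161 ± 10.7 RPKM, and the diacylglycerol kinase gene DGKA from 4.47 ± 0.11 to 56.1 ± 8.17 RPKM. RASGRP1, an exchange factor for Ras that binds diacylglycerol, fell from 7.31 to 3.96 RPKM. PRKCD and PRKCA did not pass, at 16.5 to 18.7 and 7.43 to 7.93 RPKM, and PRKCB had under 1 RPKM in all 4 libraries and was not tested. The median of this list, 0.07, was -0.04 without control replicate 2, 0.15 without control replicate 1 and 0.0408 after median-of-ratios scaling.

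The ChIP targets of the study were also read at the RNA level. CTCF, the gene of the insulator protein, fell from 44.0 ± 1.36 to 24.0 ± 1.96 RPKM (log2 fold change -0.85, SE 0.134, adjusted p = 9.80e-04). Of 19 tested genes of CTCF partners and cohesin, 1 rose, 13 fell and 5 did not pass, and 1 rose and 13 fell when adjusted over the list alone (camera, adjusted p = 0.00199; adjusted p = 0.477 with an estimated correlation). The cohesin subunit genes RAD21, SMC1A and SMC3 fell from 156 to 83.0, from 32.6 to 8.47 and from 40.4 to 21.6 RPKM. CDCA5 and ESCO2, which act on cohesin during S phase, had the largest falls, with log2 fold changes of -4.25 and -3.81.

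Linker histone genes differed in direction and level. HIST1H1C (H1.2) rose from 12.8 ± 0.46 to 60.5 ± 14.7 RPKM and HIST1H1D (H1.3) from 0.63 ± 0.229 to 2.64 ± 0.356 RPKM. H1FX, the linker histone gene with the highest values listed here, had 126 ± 9.56 RPKM in control and 92.8 ± 20.9 RPKM with TPA. It did not pass in limma (adjusted p = 0.0574), but it passed after median-of-ratios scaling (adjusted p = 0.0214), and its call also changed without TPA replicate 2. HIST1H1E had 1.17 and 1.19 RPKM and did not pass; its log2 fold change of -0.02 lay between -0.57 and 0.54 when 1 library was left out. Of these 4 linker histone genes 2 rose and 2 did not pass, and 2 rose and 1 fell when adjusted over the list alone. With the replicate number as a block 2 rose and 1 fell as well. These 4 genes are too few for a list test. HIST1H1A, H1FNT and H1FOO were listed at 0 in every library, and HIST1H1B, HIST1H1T and H1F0 stayed below the filter.

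Most histone chaperone genes fell, while most of the core histone genes tested rose. NAP1L1, a nucleosome assembly protein gene, did not pass (279 ± 23.4 RPKM in control, 236 ± 8.32 RPKM with TPA, adjusted p = 0.177), and NAP1L4 fell from 79.0 ± 6.58 to 45.3 ± 9.10 RPKM. Of 24 chaperones tested, 2 rose, 18 fell and 4 did not pass, and 2 rose and 18 fell when adjusted over the list alone (camera, adjusted p = 8.08e-05; adjusted p = 0.477 with an estimated correlation). The replication-coupled chaperone genes ASF1B and CHAF1A fell from 69.1 to 2.94 and from 50.6 to 2.53 RPKM, whereas ASF1A rose from 7.28 to 13.3 RPKM. Of 55 core histone genes 23 were tested, and 19 rose, 1 fell and 3 did not pass, and 19 rose and 1 fell when adjusted over the list alone (camera, adjusted p = 6.17e-06; adjusted p = 0.477 with an estimated correlation). HIST1H2AC rose from 7.27 ± 2.53 to 88.8 ± 42.5 RPKM and HIST1H2BD from 7.08 ± 1.19 to 77.7 ± 37.8 RPKM, and HIST2H2AC fell with a log2 fold change of -0.53. Core histone genes are near-identical to one another, so their reads could be split between copies, and with no filter on low values the list no longer passed (adjusted p = 0.139) and its median went from 1.14 to 0.0944 (1.82 with a pseudocount of 0.1 and 2.53 with the filter at 5 RPKM).

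MYC and genes of ribosome biogenesis fell. MYC went from 274 ± 2.46 to 132 ± 46.9 RPKM (adjusted p = 0.00391). Of 33 genes in this list, 0 rose, 28 fell and 5 did not pass, and 0 rose and 28 fell when adjusted over the list alone (camera, adjusted p = 1.34e-06; adjusted p = 0.392 with an estimated correlation). LDHA fell from 563 to 129 RPKM, the nucleolar genes NCL and NOP56 from 788 to 318 and from 189.9 to 65.1 RPKM, and ODC1 did not pass (568 to 667 RPKM). The genes of the ribosomal proteins themselves stayed near their control level, and of 64 tested 3 rose, 0 fell and 61 did not pass. With limma p-values adjusted over the list alone 0 rose and 0 fell, and 6 of the 64 had an unadjusted p under 0.05. Their median log2 fold change was 0.17 (camera, adjusted p = 0.0422, and adjusted p = 0.713 with an estimated correlation). The list did not pass camera with no filter on low values (adjusted p = 0.165) or with protein-coding genes only (adjusted p = 0.0516). Its call also changed without TPA replicate 2, and without either control replicate, where the prior degrees of freedom of the fit were infinite. Its median was 0.101 without TPA replicate 2 and 0.108 after quantile normalization. RPS18 was listed at 0.139 RPKM or less in every library although ribosomal protein transcripts are abundant in all cells, so a value near 0 in this table can be a failed estimate.

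Most of the cholesterol synthesis and glycolysis genes tested fell. In the cholesterol synthesis list of 23, 2 rose, 18 fell and 3 did not pass, and 2 rose and 19 fell when adjusted over the list alone (camera, adjusted p = 5.71e-04; adjusted p = 0.654 with an estimated correlation). HMGCS1 fell from 88.8 to 18.1 RPKM and DHCR7 from 62.7 ± 17.4 to 13.3 ± 4.07 RPKM, while STARD4, a sterol carrier gene, rose from 20.4 ± 1.96 to 208 ± 29.0 RPKM. Among 21 glycolysis genes 3 rose, 14 fell and 4 did not pass, and 3 rose and 14 fell when adjusted over the list alone (camera, adjusted p = 0.0628; adjusted p = 0.699 with an estimated correlation). Glycolysis as a list passed camera with no filter on low values (adjusted p = 0.0209) and with the replicate number as a block (adjusted p = 0.0307). Its call also changed without control replicate 2 and without TPA replicate 1. GAPDH fell from 1876 ± 365 to 1067 ± 171 RPKM, and the glucose transporter gene SLC2A3 rose from 3.61 to 19.4 RPKM. The call of GAPDH changed without control replicate 1, where the prior degrees of freedom of the fit were infinite. Among 46 genes of oxidative phosphorylation 3 rose, 15 fell and 28 did not pass, and 3 rose and 13 fell when adjusted over the list alone, with a median of -0.24 (camera, adjusted p = 0.0272; adjusted p = 0.745 with an estimated correlation). CYC1 fell from 211 to 95.1 RPKM and SDHC rose from 8.87 to 15.3 RPKM. The oxidative phosphorylation list did not pass camera after quantile normalization (median -0.117, adjusted p = 0.146) or with the filter at 5 RPKM (adjusted p = 0.0789). Its call also changed without TPA replicate 1, and without either control replicate, where the prior degrees of freedom of the fit were infinite. Its median was -0.124 without control replicate 2, -0.131 without TPA replicate 1 and -0.386 without TPA replicate 2.

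Most of the tested genes of adhesion and migration and of cytokines and their receptors rose. Of 23 adhesion genes tested, 16 rose, 4 fell and 3 did not pass, and 16 rose and 4 fell when adjusted over the list alone (camera, adjusted p = 7.34e-04; adjusted p = 0.477 with an estimated correlation). The β2 integrin gene ITGB2 rose from 9.68 ± 1.11 to 353 ± 14.0 RPKM and the fibronectin receptor gene ITGA5 from 37.5 to 182 RPKM, while CXCR4, the chemokine receptor that holds precursors in the marrow, fell from 66.6 to 29.6 RPKM. Of 31 cytokine genes 10 were tested, and 9 rose, 1 fell and 0 did not pass, and 9 rose and 1 fell when adjusted over the list alone (camera, adjusted p = 1.05e-04; adjusted p = 0.475 with an estimated correlation), and with no filter on low values the list passed with a median of 0.305 against 2.38. IL2RA and IL21R rose from 0.0075 to 9.52 and from 1.72 to 23.4 RPKM, and TGFB1 from 22.9 to 89.1 RPKM. Among 22 interferon response genes 11 rose, 2 fell and 9 did not pass, and 11 rose and 2 fell when adjusted over the list alone (camera, adjusted p = 0.0199; adjusted p = 0.699 with an estimated correlation). IFI6 and IRF9 rose from 1.94 to 14.9 and from 3.43 to 20.1 RPKM, and HERC5 fell from 18.3 to 1.73 RPKM. The interferon list did not pass without TPA replicate 2 (median 0.223 against 0.584, adjusted p = 0.135), with no filter on low values (adjusted p = 0.085) or with the filter at 5 RPKM (adjusted p = 0.0548), and its median was 1.04 without TPA replicate 1.

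Genes of cell death and of stress responses went both ways. Of 15 BCL2 family genes tested, 9 rose, 5 fell and 1 did not pass, and 9 rose and 5 fell when adjusted over the list alone (camera, adjusted p = 0.139; adjusted p = 0.686 with an estimated correlation). The proapoptotic genes BMF and BCL2L11 (BIM) rose from 0.503 ± 0.105 to 30.6 ± 7.98 and from 16.4 ± 0.686 to 52.5 ± 12.3 RPKM, and BCL2, which opposes them, fell from 22.7 ± 0.175 to 8.88 ± 1.46 RPKM. BID, which is also proapoptotic, went the other way and fell from 25.9 ± 3.28 to 5.77 ± 1.94 RPKM. Of 23 p53 target genes 9 rose, 10 fell and 4 did not pass, and 10 rose and 11 fell when adjusted over the list alone, with a median of -0.31 and a mean of 0.13, which differ in sign (camera, adjusted p = 0.832; adjusted p = 0.951 with an estimated correlation). SESN1 rose from 6.72 to 47.9 RPKM and MDM2 fell from 95.8 to 32.2 RPKM. Of 20 genes of the unfolded protein response 6 rose, 5 fell and 9 did not pass, and 5 rose and 5 fell when adjusted over the list alone, with a median of 0.14 and a mean of -0.05 (camera, adjusted p = 0.814; adjusted p = 0.883 with an estimated correlation); the median was 0.0808 without control replicate 1 and 0.223 without control replicate 2. EDEM1 fell from 170.4 to 35.7 RPKM and PPP1R15A rose from 9.23 to 26.0 RPKM.

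Markers of other blood lineages were few. Of 17 T-cell genes only 5 were tested, of which 4 rose (CD28, LAT, GATA3 and ZAP70) and 1, BCL11B, fell, with the same counts adjusted over the list alone (camera, adjusted p = 0.0272; adjusted p = 0.477 with an estimated correlation); CD28 rose from 0.0065 to 16.3 ± 2.17 RPKM, and the list did not pass with no filter on low values (adjusted p = 0.21). Of 22 myeloid genes 5 were tested, and 3 rose, 1 fell and 1 did not pass, likewise 3 and 1 adjusted over the list alone (camera, adjusted p = 0.0895; adjusted p = 0.654 with an estimated correlation); FCER1G rose from 0.0935 to 39.7 RPKM, and CEBPA fell from 4.78 to 1.90 RPKM. The call of the myeloid list changed without control replicate 1 or control replicate 2, where the prior degrees of freedom of the fit were infinite. None of the 11 erythroid genes reached the filter. Of 17 commonly used reference genes 1 rose, 10 fell and 6 did not pass, and 1 rose and 10 fell when adjusted over the list alone (camera, adjusted p = 0.0862; adjusted p = 0.514 with an estimated correlation), and this list passed with no filter on low values (adjusted p = 0.0391). ACTB did not pass (1720 to 1675 RPKM), and TUBA1B fell from 773 ± 72.9 to 74.2 ± 3.78 RPKM.

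**Figure D3:**
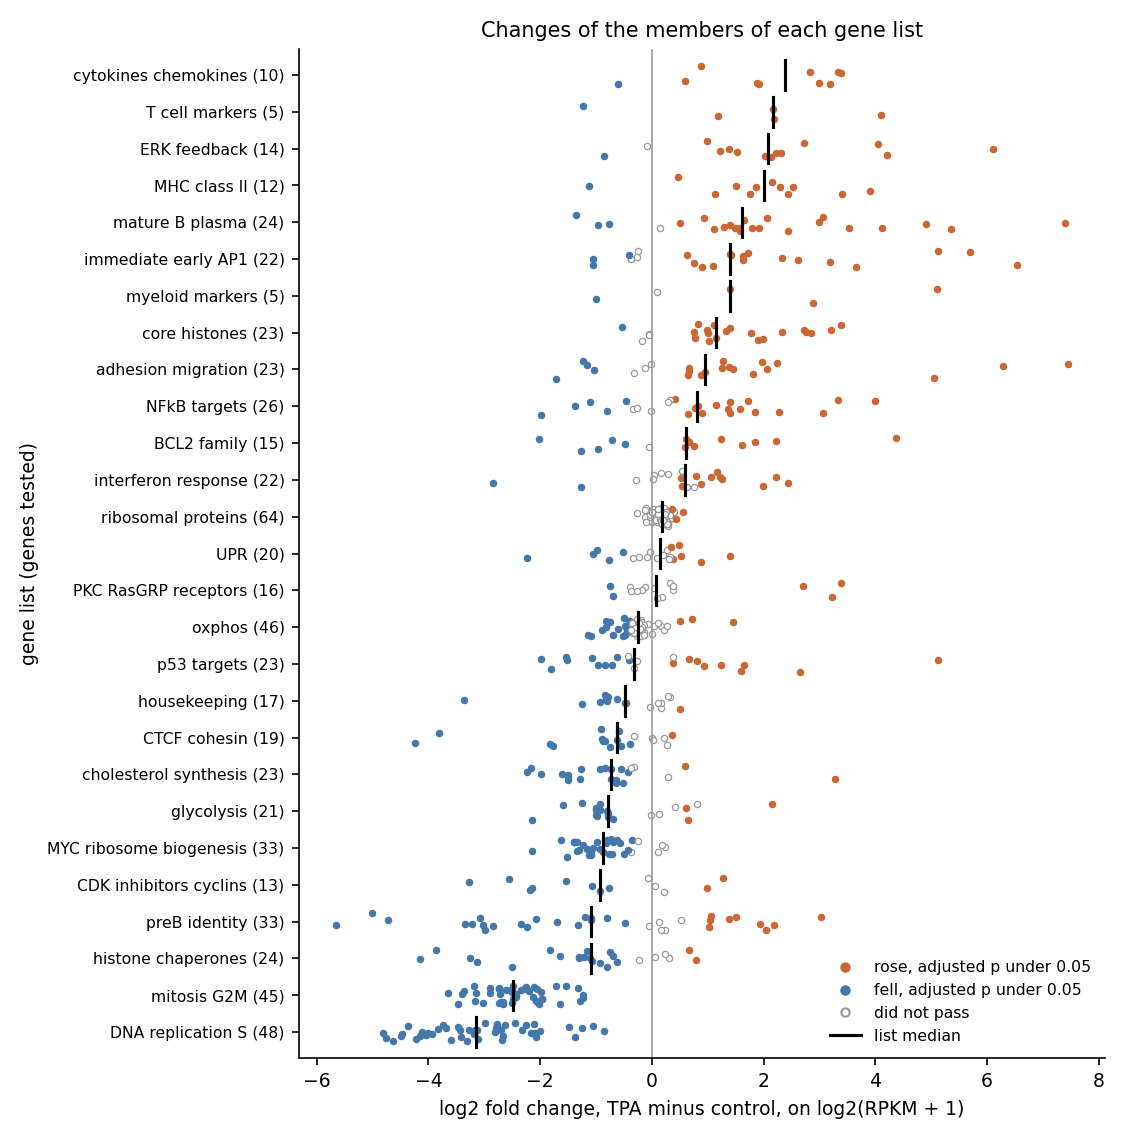
Log2 fold change, TPA minus control on log2(RPKM + 1) (horizontal axis), of each tested member of 27 of the 28 gene lists with at least 5 tested genes (vertical axis, number tested in brackets); filled points passed an adjusted p under 0.05, open points did not, and black bars are list medians. All 48 replication and all 45 mitosis genes lie left of 0, and list medians run from -3.15 for replication to 2.38 for cytokines (0.305 with no filter on low values).

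Of 30 lists, 28 had the 5 members needed for the camera test, which compares a list with the other genes, and 19 passed with a preset correlation of 0.01, 11 upwards and 8 downwards. With the correlation between members estimated from these 4 libraries none passed, with 3 at an unadjusted p under 0.05, while limma's fry, which asks only whether members move to 1 side, passed 19, of which 15 were among those of camera. The interferon, ribosomal protein, cholesterol synthesis and oxidative phosphorylation lists passed camera but not fry, and the phorbol ester receptor, BCL2 family, myeloid and reference gene lists passed fry but not camera. A gene can pass the filter through the 2 libraries of 1 group, so the share of rises among tested members describes part of a list. With no filter on low values the median went from 2.16 to 0.0122 for T-cell markers, from 1.40 to 0.0370 for myeloid markers, from 1.40 to 0.916 for immediate early genes, from 2.08 to 1.38 for ERK feedback genes and from -0.93 to -0.0674 for cyclins and their inhibitors. The medians of all 28 lists kept their sign under median-of-ratios scaling and quantile normalization.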

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

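Of the alternatives, only the restriction to protein-coding genes was chosen after the data were seen. The count of genes changed by TPA (7075) ranged from 5250 at an adjusted p threshold of 0.01 to 8234 with the replicate block. The count changed by at least 2-fold (2825) ranged from 2240 to 3486. Each stayed within 1.5 times of its value under every alternative it was run with, pseudocount, filter and left-out library included. The 2-fold count was not run at the other adjusted p thresholds, and the count of all changed genes was not run with treat. Of the genes called without a filter (7234), 5779 were also called with it, and after median-of-ratios scaling 7007 of 7568 were shared. The share of rises among the calls lay between 44.62% and 53.59%. Among 137 named genes, 118 kept their direction and their side of the threshold wherever they were tested, and 19 did not in at least 1 alternative.

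Of the settings, camera with an estimated correlation changed the list results most, passing 0 of 28 lists against 19 with the preset one. With it, 3 lists had an unadjusted p under 0.05. This setting allows for members that vary together, but that alone does not account for the loss. It also works with only the 2 residual degrees of freedom of the fit, so it can pass few lists. Even the S-phase list, in which all 48 tested genes fell, had an unadjusted camera p of 0.0812 with it. The ERK feedback list had an estimated correlation of -0.075, below the preset 0.01. Its unadjusted camera p still went from 1.32e-06 to 0.0358. In the other alternatives 5 lists lost their call at least once (oxidative phosphorylation and ribosomal proteins in 5 each, interferon response in 3, core histones and T-cell markers in 1 each) and 4 gained one (pre-B identity in 5, glycolysis in 4, myeloid markers in 2, reference genes in 1). These counts include the fits without a control replicate, whose p-values cannot be set against the main ones. Directions reversed only for results whose value with all libraries was close to 0: ETV5 went to 0.0614 after quantile normalization, and with 1 library left out HIST1H1E ranged from -0.57 to 0.54 (0.43 without control replicate 2 and 0.54 without TPA replicate 1), ACTB from -0.0811 to 0.0044 (0.0028 without control replicate 1) and the median of the phorbol ester receptor list from -0.0364 to 0.15. The cause was not tested for ETV5, and for the others leaving out 1 library was enough to change the sign.

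The groups share replicate numbers, but nothing in the labels says that a number marks a shared culture or day. As a paired check, the differences between replicates 1 and 2 in control correlated with those in TPA at r = 0.361 across genes, and the fit with the replicate block called 8234 genes (3946 rose, 4288 fell) and 20 lists, the added list being glycolysis (adjusted p = 0.0307). With the block 4 oxidative phosphorylation genes rose and 26 fell of 46 (3 and 15 without it). In the phorbol ester receptor list 5 genes rose and 5 fell of 16 (3 and 2 without it). Rises went from 3 to 9 among ribosomal proteins, from 3 to 5 in glycolysis and from 1 to 3 among reference genes. Depth limits the low genes most: an RPKM near 0 rests on a few reads, and neither the depth of the libraries nor reads shared between copies can be worked out from these values.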

Other observations

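The gene families in this part, the hypoxia-response list, the correlation of neighbouring genes and the tests of untreated-like cells and of HLA-B were chosen after the results had been seen. Metallothionein genes, which buffer zinc and copper, fell in all 5 cases tested, of 13 in the table (median log2 fold change -2.13). MT1X fell from 540.5 and 495.6 RPKM in the control libraries to 23.2 and 31.8 RPKM with TPA, and MT2A from 46.9 and 49.5 to 10.8 and 23.3 RPKM. Of 83 interleukin and interleukin receptor genes 19 were tested, and 17 of these rose. IL24 rose from 2.33 and 2.35 to 80.6 and 100.1 RPKM, and IL15RA, which presents interleukin-15, from 3.88 and 4.68 to 39.5 and 41.9 RPKM, while IL7R and IL17D fell. IL2RA, IL2RB and IL1RN, at 0.125 RPKM or less in both control libraries, passed the filter through the TPA libraries. Of 10 Toll-like receptor genes 6 were tested, of which 5 rose (TLR1, TLR4, TLR6, TLR9 and TLR10) and TLR3 fell; all 5 that rose were under 1 RPKM in both control libraries and passed the filter through the TPA libraries, so this share of rises follows from the filter. TLR9, a receptor for unmethylated DNA in B cells, went from 0.407 and 0.283 to 11.03 and 6.75 RPKM.

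Of 20 nucleoporin genes tested, of 23 in the table, 15 fell and 5 did not pass (median log2 fold change -1.05). NUP35 went from 13.1 and 16.3 to 3.52 and 3.53 RPKM. All 8 genes tested of the CCT chaperonin list, of 9 in the table, fell (median -0.738), with TCP1 going from 174 and 211 to 69.0 and 70.6 RPKM. This chaperonin folds actin and tubulin. Of 10 RNA exosome genes 7 fell and 3 did not pass (median -0.862). Of 28 kinesin genes tested, of 39 in the table, 19 fell and 3 rose (median -1.33). Those that rose were KIF3A, KIF3B and KIF3C, motor subunits of the kinesin-2 complexes. Among those that fell, KIF11, KIF20A, KIF23, KIF2C and KIF4A also belong to the mitosis list, so the fall of kinesin genes partly repeats the result of that list. Of 7 genes tested of Bardet-Biedl syndrome, a disease of cilia, 6 rose (median 0.887; BBS9 and BBS12 passed the filter through the TPA libraries), with BBS4 going from 3.66 and 3.49 to 9.21 and 11.8 RPKM. Semaphorin genes rose in 9 and fell in 2 of 13 cases tested, of 20 in the table (median 0.801). Of those that rose, SEMA7A, SEMA4A, SEMA3B and SEMA3F passed the filter through the TPA libraries, so this share of rises is partly set by the filter. SEMA5A, which fell, passed through the control libraries.

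Protein-coding genes of 6p21.32 and 6p21.33 were listed near 0: 11 of 130 averaged 1 RPKM or more (8 of 15 HLA genes but 3 of 115 others), against 60.9% in 6p21.31, and RPS18, TUBB and DAXX were among the genes at 0.212 RPKM or less in every library. Loss of the region from these cells is argued against by HLA-B, which lies inside it and had at least 165 RPKM in every library. A candidate explanation is that reads of this region were lost to alternate copies in the hg19 reference, which begin inside 6p22.1. As that would require, 7 genes of 6p22.1 on the inner side of that edge had a median of 0.0528 RPKM (quartiles 0.00138 and 0.837, with ZNRD1 at 8.70 as the exception), against 3.62 RPKM (quartiles 2.25 and 9.41) for 7 genes on the outer side. Silencing of the region was not tested, and with this candidate explanation the listed zeros of TNF, LTA, LTB and IER3 would say nothing about their expression.

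Core histone genes rose (19 of 23 tested, of 55 in the table, with a median of 0.0944 with no filter on low values) while all 48 S-phase genes fell. Scaling of the libraries is argued against for the 23 tested genes, since their median was 0.951 after quantile normalization, above the replicate difference of 0.275. The filter favours rises among these genes, so this does not extend to all 55. Reads moving between near-identical histone genes are argued against too, since RPKM summed over all 55 core histone genes was 84.6 and 73.2 in control and 285 and 448 with TPA (log2 ratio 2.21, spread between replicates 0.653). A rise of the members known to have polyadenylated transcripts, which cells make outside S phase, may contribute: all 7 such members rose, with a median of 1.78 against 1.01 for the 16 others, but the difference of 0.763 had a permutation p of 0.206 (two-sided, 100000 resamples). With 7 members this explanation cannot be told apart from a rise of the tested core histone genes in general. The comparison covers tested members only, and the filter favours rises among them. HIST1H3D, for example, passed the filter through the TPA libraries (0.464 and 0.43 RPKM in control, 5.62 and 6.99 RPKM with TPA). How the RNA was selected before sequencing is not described here, so histone transcripts without a poly(A) tail may be missing from all these values. The rise is therefore that of the histone transcripts listed, and a rise of histone transcripts in general was not tested.

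Pre-B transcripts were higher in TPA replicate 2 than in TPA replicate 1: of the 12 pre-B identity genes that fell by 4-fold or more, 11 were higher there (median ratio 1.90), with IGLL1 at 2.69 and VPREB1 at 2.83 times. Untreated-like cells in that library are argued against for the 12 genes as a set, because they would bring S-phase transcripts too. The median S-phase excess was 0.578% of the control mean (quartiles -0.297 and 2.07) against 5.55% (quartiles 3.55 and 8.33) for the pre-B genes. The pre-B excess ran from -0.171% for MME to 11.3% for MYB, and that of IGLL1, at 1.8%, lay inside the S-phase quartiles. Scaling is argued against by the median ratio of all genes, 0.134 on the log2 scale, against 0.844 (quartiles 0.676 and 1.02) for the pre-B genes. A weaker overall response in replicate 2 cannot be told apart from an equal one: genes that rose by 4-fold or more had moved 1.01 times as far as in replicate 1 (quartiles 0.933 and 1.1), and the other genes that fell 0.955 times (quartiles 0.89 and 1.01). A difference in exposure time, which the labels give only as a range, stays open as untested.

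Hypoxia-response genes were higher in replicate 1 than in replicate 2 of both groups, in 22 of 22 cases in control and 17 of 22 with TPA, with median log2 differences of 0.431 and 0.159, against -0.049 and -0.134 for all genes tested. BNIP3, a member, was at 17.7 and 10.1 RPKM in the control libraries and at 5.59 and 4.88 RPKM with TPA. Log2 fold changes of genes next to each other on a chromosome, with the order taken from the RefSeq annotation of GRCh38, correlated at 0.172 over 10623 pairs. The highest of 1000 shuffles of such pairs was 0.0308. Among next genes that do not overlap or share a symbol stem, the correlation was 0.129 over 9105 pairs. For the tenth gene along it was 0.035, and no shuffle was run for either of these sets. These are correlations across genes, which are not independent.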
